A study of Mus musculus with 2 samples.

How the data were processed

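Droplet-based 3' RNA sequencing (10x Chromium) was available for 2 libraries of cells from parietal bone defects of wild-type C57BL/6 mice, 1 per hydrogel (CGG and CGG-Cit), taken 14 days after surgery. Per the labels, defects measured 2 mm, the trimmed tissue was digested in 0.3% collagenase, and the cells passed a 70 µm strainer. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization; every value was a whole number and the shallowest barcode in each library held 500 UMIs. Per the file headers the counts were made with Cell Ranger 4.0.0, whereas the processing notes name Cell Ranger 3.0, and the genome build was mm10. The labels name kit version 2 or 3 without saying which. Both matrices list the same 27998 genes. The reads themselves were not used here.

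The analysis used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, statsmodels 0.14.6 and matplotlib 3.10.9. The groups, filters, gene lists, marker lists, list and class pairs, and the rule for named genes were fixed before the data were examined. Barcodes were kept with at least 200 detected genes and at most 20% mitochondrial UMIs. In the CGG library 56 barcodes had too few genes and 192 (1.53%) too many mitochondrial UMIs; in the CGG-Cit library these were 236 and 39 (0.361%). Predicted doublets were removed with Scrublet in each library. Its own threshold marked 560 of 10531 CGG-Cit cells (5.32%) but 1 of 12279 CGG cells, which is under the preset minimum of 0.5%, so the preset fallback of 0.8% per 1000 barcodes applied to CGG and removed the 1231 highest-scoring cells (10.0%). This left 11048 CGG cells with 82107891 UMIs and 9971 CGG-Cit cells with 95450556 UMIs, with median mitochondrial shares of 1.86% and 1.61%.

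Cells of both libraries were scaled to 10000 UMIs, log-transformed and clustered together without batch integration, on 2000 variable genes (scaled to a maximum of 10), 30 principal components, 15 neighbours and Leiden resolution 1.0 with a fixed seed of 7. Each cluster was named by the marker list with the highest mean log2 ratio over its 8 best markers, the ratio being the cluster's CPM over that of all other cells with 5 CPM added to each. At least 3 markers of the list had to be detected in a share of 0.10 of the cluster's cells at a ratio of 2 or more. A cluster stayed unnamed where this failed, where its 10 top genes (detected in a share of at least 0.25 of cells) held more markers of another class, or where its median depth was under 0.333 of the library's with no marker among the top genes. Marker lists covered neutrophils, monocytes and macrophages, dendritic cells, osteoclasts, mast cells and basophils, T and NK cells, B lineage, plasma cells, erythroid cells, myeloid progenitors, platelets, mesenchymal cells, osteoblasts, chondrocytes, endothelial and mural cells, glia, brain, muscle, epithelium and fat. The mesenchymal lineage joins mesenchymal, osteoblast and chondrocyte clusters; in the main clustering no cluster was named osteoblast, chondrocyte, osteoclast, plasma cell, platelet, glia, brain, muscle, epithelium or fat.

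Shares are given with exact Clopper-Pearson 95% intervals and differences in percentage points (CGG-Cit minus CGG) with Newcombe 95% intervals. Gene levels are UMIs summed over a class and library, as CPM (UMIs per 1000000 UMIs of the class), with exact Poisson intervals, and ratios with exact conditional binomial intervals. A class needed at least 100 cells in each library. The mesenchymal lineage (62 CGG-Cit cells) and endothelial cells (46) fell below and are reported with that stated, a choice made after seeing the data. Cxcl12 and Cxcr4 are also given in other classes below this minimum. A gene with 0 UMIs was set against a floor of 3 UMIs. With 1 library per group no test, p-value or count of changed genes was possible, since cells are not replicates.

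Gene lists were summarised by the median log2 CPM ratio with 0.5 UMI added, over members with a mean of at least 10 CPM and at least 20 UMIs in both libraries together. The interval came from 2000 redraws of the summed counts, and the percentile from 10000 random lists matched on size and mean CPM. The lists covered osteogenic, mesenchymal progenitor, extracellular matrix, tricarboxylic acid cycle, citrate and acetyl-CoA, histone acetyltransferase, histone deacetylase, glycolysis, oxidative phosphorylation, recruitment ligand, recruitment receptor, neutrophil chemoattraction, primary granule, secondary and tertiary granule, pro-inflammatory, alternative activation, antigen presentation, interferon response, cell cycle, dissociation stress and angiogenesis genes. Named genes were, in each of the mesenchymal lineage, neutrophils, and monocytes and macrophages, the 8 highest and 8 lowest by the bound of the ratio's interval nearest to 1. They needed at least 50 CPM and 30 UMIs in the higher library and a class level of at least 0.5 of that over all kept cells there. Mitochondrial, ribosomal, hemoglobin, antigen receptor, Gm- and Rik-named and sex-linked marker genes were left out. To these came up to 4 members per list with the largest ratio among those with at least 50 CPM, the title's targets (Acly, Slc25a1, Slc13a5, Ep300 and Kat2a in the mesenchymal lineage), and Cxcl12 and Cxcr4 in every class. Genes quoted only to name clusters or as markers of other cells (C1qa, S100a8, Gm26870, Bglap and Il17a) were chosen after their values were seen. Positions come from GENCODE M21 (GRCm38), in which 162 of 162 named genes were found by the identifier in the deposited gene table.

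The step for gene levels was tested on simulated data, in which 50 genes each were given a log2 change of 1, -1, 2 or -2 at the depth of each class. In neutrophils (5493 genes) the median estimates were 1.00, -1.02, 2.00 and -1.99, in monocytes and macrophages (7288 genes) 0.97, -1.05, 1.98 and -2.05, and in the mesenchymal lineage (8558 genes) 0.99, -0.94, 1.98 and -2.02. Intervals of unchanged genes held the true ratio in 95.2%, 94.9% and 95.5% of cases. The class sums were drawn as Poisson counts, the model behind the intervals, so this coverage leaves out spread between cells and between mice. Settings fixed in advance and tried beside the main ones were resolutions 0.5 and 2.0, doublets kept, at least 500 detected genes, at most 10% mitochondrial UMIs, thinning to 1000 UMIs per cell (which left out 702 CGG and 258 CGG-Cit cells), separate clustering, median-of-ratios size factors, no minimum level for list members, members not set by free RNA, and mesenchymal clusters alone. Settings chosen after seeing the data were an equal share of doublets removed, leaving out clusters led by Gm26870, haematopoietic classes only, a common mix of clusters within a class, and the Ptgds cluster alone.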

Results

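Cells were profiled by droplet-based RNA sequencing from 2 mm defects in the parietal bone of wild-type C57BL/6 mice, 14 days after a hydrogel had been placed in the defect. The design holds 2 groups with 1 library each, defects filled with CGG hydrogel and defects filled with CGG-Cit hydrogel. Neither abbreviation is spelled out in the labels, and the number of mice behind a library is not given in the sources used here. The CGG library held 12527 cell barcodes and 92517884 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), with a median of 3819 UMIs and 1440 genes per barcode. The CGG-Cit library held 10806 barcodes and 106173570 UMIs, with medians of 6212.5 UMIs and 1525 genes. After filtering, 11048 CGG cells (median 3969 UMIs) and 9971 CGG-Cit cells (median 5903 UMIs) were kept. Without replicates no difference between the hydrogels could be tested, and every interval given is a 95% interval that covers counting error only.

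The first comparison addressed the stated question of which cell populations occupied the defect. The defects differed in stromal cells and in cells of the marrow lineages. Mesenchymal lineage cells, marked by collagens and by genes such as Pdgfra and Prrx1, made up 34.2% of CGG cells (33.3 to 35.1%, 3780 cells) and 0.622% of CGG-Cit cells (0.477 to 0.796%, 62 cells), a share 55.0-fold lower with CGG-Cit. Neutrophils made up 10.1% of CGG cells (9.50 to 10.6%, 1111 cells) and 26.7% of CGG-Cit cells (25.9 to 27.6%, 2667 cells), a ratio of 2.66. Monocytes and macrophages went the other way, with 14.7% of CGG cells (14.0 to 15.4%, 1624 cells) and 5.19% of CGG-Cit cells (4.76 to 5.64%, 517 cells). B lineage cells showed the widest gap in percentage points among the immune classes, at 8.31% (7.80 to 8.84%, 918 cells) with CGG and 38.9% (38.0 to 39.9%, 3882 cells) with CGG-Cit.

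Vessel cells followed the mesenchymal lineage. Endothelial cells were 6.25% of CGG and 0.461% of CGG-Cit cells (690 and 46 cells), and mural cells, which wrap small vessels, were 1.955% and 0.120% (216 and 12 cells). Erythroid cells were 5.58% and 10.3% (617 and 1030 cells). Myeloid progenitors, marked by Elane, Mpo and Prtn3, were 0.326% and 2.39% (36 and 238 cells), and mast cells and basophils were 0.208% and 0.682%. T and NK cells (6.47% and 5.70%) and dendritic cells (0.923% and 1.003%) differed least by ratio among the named classes, and the interval of the dendritic difference included 0 (-0.185 to 0.349 percentage points); with each library clustered alone that difference was -2.99. Clusters that no marker list named held 11.01% and 7.83% of cells (1216 and 781). These were unlike in the 2 libraries, with 992 CGG and 26 CGG-Cit cells in a cluster led by Gm26870 and Col1a1, 155 and 464 in one led by F13a1 and Tifab, and 69 and 291 in one led by Car1 and Sdsl.

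**Figure D1:**
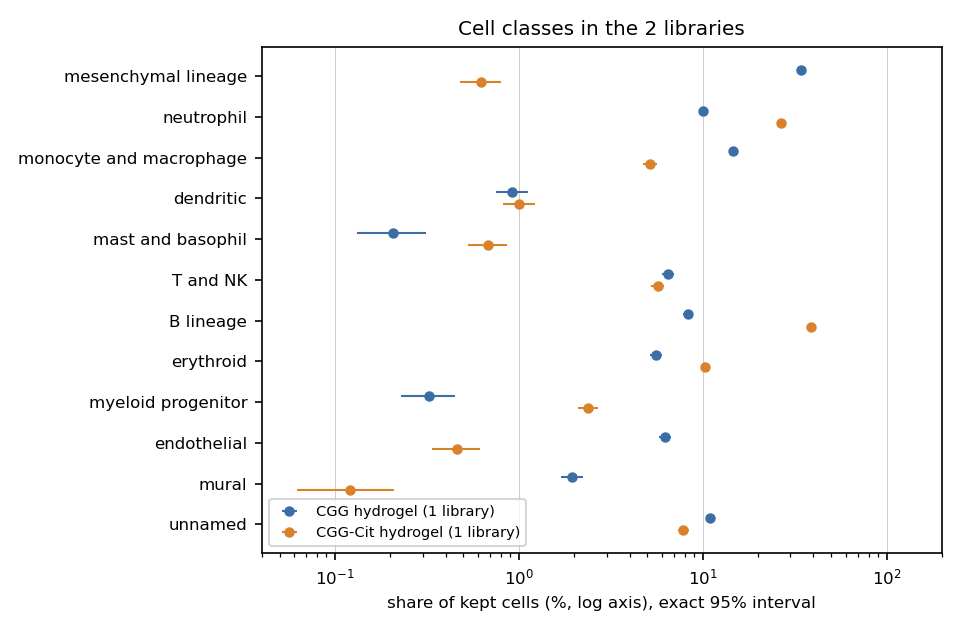
Share of kept cells in each class, in percent on a log axis, for the CGG library (blue) and the CGG-Cit library (orange), 1 library each, with exact 95% intervals for counting error as bars. The mesenchymal lineage point lies at 34.2% for CGG and 0.622% for CGG-Cit, while the B lineage point lies at 8.31% and 38.9%.

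Among the haematopoietic classes alone, which removes the stromal cells from the denominator, neutrophils were 21.6% of CGG and 29.4% of CGG-Cit cells, a difference of 7.82 percentage points (6.34 to 9.27). Monocytes and macrophages were 31.6% and 5.70%, B lineage cells 17.8% and 42.8%, and T and NK cells 13.9% and 6.26%. The erythroid difference turned direction in this view, at 11.99% and 11.4% (-0.634 percentage points, -1.75 to 0.455), and its interval included 0. The B lineage cells were mostly immature. The cluster led by Rag1, which cuts DNA in antigen receptor assembly, held 336 CGG and 1710 CGG-Cit cells, and the cluster led by Dntt, which adds bases in that assembly, held 128 and 316. A cluster led by Nrgn and Bfsp2, with the surrogate light chain genes Igll1 and Vpreb1 among its top genes, held 52 and 479. A cluster with histone genes among its top genes held 78 and 657, and the cluster led by Ms4a1, a marker of more mature B cells, held 324 and 720.

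The shares of some classes depended on the clustering and on whether the clusters led by Gm26870 were included. The cluster with the most CGG cells (2073 CGG and 6 CGG-Cit cells) was led by Gm26870 and Col1a1 and had a median depth of 0.474 times the median of its library. At the coarser resolution of 0.5 the mesenchymal difference was -11.5 percentage points instead of -33.6, and the unnamed difference -27.3 instead of -3.17. Without the clusters led by Gm26870 the mesenchymal difference was -20.8, with each library clustered alone it was -20.6, and in the latter setting the monocyte and macrophage difference was -1.48 instead of -9.51 percentage points. With each library clustered alone the mesenchymal share was 13.3-fold lower with CGG-Cit (167 CGG-Cit cells), against 22.5-fold at resolution 0.5 and 38.0-fold without the clusters led by Gm26870. The myeloid progenitor difference turned to -0.837 with each library clustered alone, and the unnamed difference turned to 4.79 without the clusters led by Gm26870.

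The next comparison concerned neutrophils, which the series title names as stimulators of mesenchymal stem cell recruitment. Interferon response genes and primary granule genes were higher in CGG-Cit neutrophils, while recruitment ligands and pro-inflammatory genes were mostly lower. Of 12 measured interferon response genes 11 were higher, with a median log2 ratio (CGG-Cit over CGG) of 1.19 (1.02 to 1.28), above all 10000 matched random lists. Rsad2 (ENSMUSG00000020641; chromosome 12, 26442746 to 26456452, GRCm38), an antiviral enzyme, had 29.5 CPM (UMIs per 1000000 UMIs of the class) with CGG and 79.6 CPM with CGG-Cit, a ratio of 2.70 (2.36 to 3.09). Isg15, a ubiquitin-like protein, had 71.1 and 176 CPM (ratio 2.47, 2.27 to 2.70) and Oasl2 a ratio of 2.46. Outside the list, Ifi27l2a (ratio 2.47) and Rtp4 (2.53), both interferon-induced, were among the 8 genes named as highest, but Ifi27l2a was also higher in B lineage cells (569 and 1192 CPM, against 389 and 964 CPM in neutrophils).

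The interferon genes were higher beyond counting error in 3 of the 4 neutrophil clusters. The median log2 ratio was 1.36 in the cluster led by Ly6g and Ltf, 0.84 in the one with Stfa2l1 and Il1b among its top genes, and 1.92 in the one led by Retnlg and Mmp8. In the immature cluster led by Chil3 and Camp it was 0.26 (-0.04 to 0.45). B lineage cells, used here as background for free RNA, went the other way, with a summed level of 439 CPM with CGG and 313 CPM with CGG-Cit, against 425 and 790 CPM in neutrophils. Erythroid cells, however, were higher by 358 CPM (324 to 391), about as much as neutrophils (365 CPM). Under 3 neutrophil members remained once those set by free RNA were left out, so a part played by free RNA stays open. With members included whatever their level, the neutrophil median was 0.70.

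**Figure D2:**
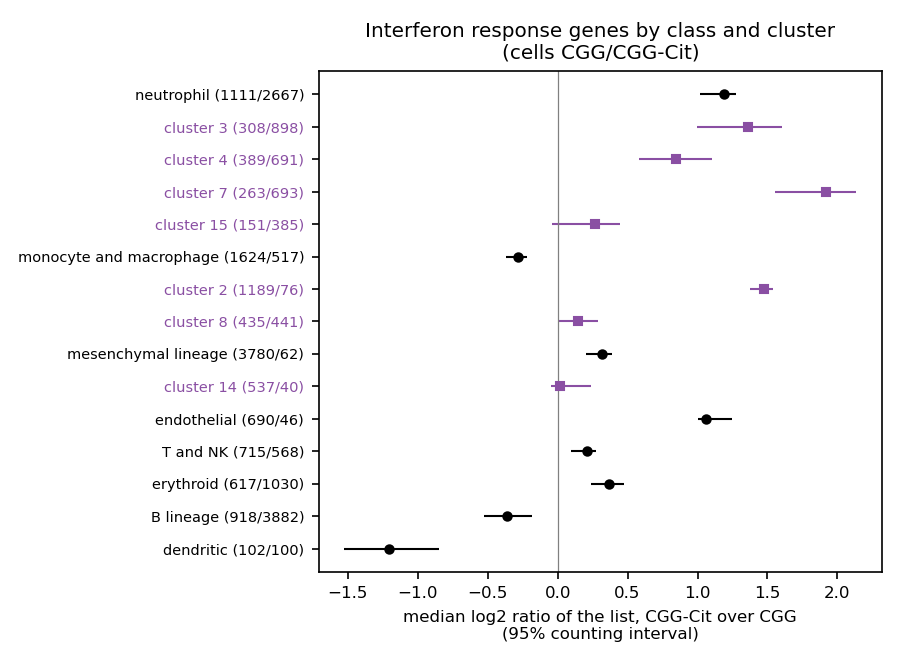
Median log2 ratio (CGG-Cit over CGG) of interferon response genes in each class (black) and in clusters within a class (purple), 1 library per group, with 95% counting intervals as bars and the number of cells in each library in brackets. The medians were 1.19 in neutrophils, 1.48 in the C1q macrophage cluster 2 and -1.21 in dendritic cells.

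Primary granule genes, which encode the proteases packed during early neutrophil maturation, were higher for 6 of 7 measured members (median log2 ratio 1.07, 0.90 to 1.15). Elane (ENSMUSG00000020125; chromosome 10, 79886247 to 79888215) had 104 and 294 CPM and Prtn3 113 and 238 CPM, while Serpinb1a, an inhibitor of these proteases, had 411 and 667 CPM. The same list had a median of 1.74 in B lineage cells, which are not known to make these proteases, and Elane stood there at 12.9 and 53.0 CPM. It was also higher in T and NK cells (1.55) and monocytes and macrophages (1.87), but lower in the mesenchymal lineage (-1.04) and endothelial cells (-3.69). The summed level rose by 122 CPM in B lineage cells and, by neutrophil cluster, from 62.3 CPM (Retnlg) to 1175 CPM (Chil3). Under 3 neutrophil members remained once those set by free RNA were left out. With at least 500 detected genes per cell the neutrophil median was 1.74. Secondary and tertiary granule genes had 9 of 15 members higher and a median of 0.12 (0.12 to 0.13), with Chil3 and Camp at ratios of 1.26 and 1.20; with median-of-ratios scaling the median was 0.22. Within clusters it was 0.13 in the Ly6g cluster but -0.16 (-0.28 to -0.07) in the Stfa2l1 cluster, -0.23 (-0.31 to -0.18) in the Retnlg cluster and -0.14 in the Chil3 cluster. Cell cycle genes had 17 of 20 higher (median 0.32, 0.25 to 0.36), among them Stmn1 (ratio 1.67) and Cdk1 (1.45), and at a common mix of the neutrophil clusters this median was 0.16. It was lower in the Ly6g cluster (-0.17, -0.31 to -0.02) and the Retnlg cluster (-0.24, -0.39 to -0.07) and higher in the other 2 (0.79 and 0.21). Stmn1 and Cdk1 stood higher in B lineage cells (1072 and 1834, 113 and 215 CPM) than in neutrophils (230 and 383, 66.6 and 96.4 CPM).

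Recruitment ligands, secreted signals known to attract or expand progenitors, had 3 of 11 members higher and a median of -0.68 (-0.81 to -0.54). Osm (ENSMUSG00000058755; chromosome 11, 4236420 to 4241026), which encodes oncostatin M, a cytokine known to promote osteoblast formation, was the clear exception at 254 CPM with CGG and 523 CPM with CGG-Cit (ratio 2.06, 1.964 to 2.15). Spp1 (ratio 0.274), which encodes osteopontin, Sema4d (0.561) and Vegfa (0.625) were lower. Spp1 was also lower in B lineage cells (78.5 and 11.6 CPM), and with only the members whose level was not set by free RNA the list median was -0.34, against -0.43 with doublets kept. The median was -0.26 in the Ly6g cluster, -0.89 in the Stfa2l1 cluster, -0.96 in the Retnlg cluster and -0.09 (-0.37 to 0.09) in the Chil3 cluster. The summed level was higher in the Stfa2l1 (9124 and 11234 CPM) and Ly6g (1148 and 1200 CPM) clusters. It was lower in the Chil3 cluster (1822 and 1677 CPM), and in the Retnlg cluster (3208 and 3309 CPM) the interval of the difference included 0.

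Neutrophil chemoattraction genes had 2 of 12 members higher (median -0.33, -0.37 to -0.29), with the chemokines Ccl3 at a ratio of 0.454, Ccl4 at 0.549 and Cxcl2 at 0.639, and the G-CSF receptor Csf3r at 0.736. Pro-inflammatory genes had 3 of 10 higher (median -0.62, -0.70 to -0.51). Tlr2, a sensor of bacterial lipoproteins, had a ratio of 0.467 and the inflammasome gene Nlrp3 of 0.489. At a common mix of clusters these medians were -0.13 and -0.30, and with members included whatever their level they were -0.65 and -1.10. Both lists were also lower in B lineage cells, with medians of -1.94 (0 of 6 higher) and -1.90 (0 of 7 higher). Their summed levels differed by -282 and -145 CPM there, against -1268 and -843 CPM in neutrophils. Within clusters the chemoattraction sum differed beyond counting error only in the Chil3 cluster (-561 CPM), and the median was 0.00 (-0.08 to 0.06) in the Ly6g cluster. The pro-inflammatory sum was higher in the Stfa2l1 cluster (1445 CPM). It was lower in the Ly6g (-269 CPM), Retnlg (-419 CPM) and Chil3 (-385 CPM) clusters. The pro-inflammatory median was below 0 in every cluster (-1.87 to -0.27).

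Most metabolic and chromatin lists differed little in neutrophils, while citrate and acetyl-CoA genes were mostly lower. Tricarboxylic acid cycle genes had 11 of 18 members higher (median 0.06, -0.01 to 0.18), with Sdhb at a ratio of 1.37 and Mdh2 at 1.24. Citrate and acetyl-CoA genes had 1 of 5 higher (-0.28, -0.46 to -0.14), with a median of -0.82 when members were included whatever their level, -0.63 with only the members not set by free RNA, and -0.85 to -0.29 across the 4 clusters. Glycolysis genes had 8 of 15 higher (0.03, -0.01 to 0.08), although the lactate exporter Slc16a3 had 696 and 313 CPM. Oxidative phosphorylation genes had 14 of 25 higher (0.01, -0.04 to 0.07), histone acetyltransferase genes 5 of 13 (-0.11, -0.18 to 0.01) and histone deacetylase genes 3 of 8 (-0.08, -0.19 to 0.07); the deacetylase median was 0.02 with median-of-ratios scaling and 0.03 with doublets kept. Dissociation stress genes had 9 of 18 higher (-0.01, -0.05 to 0.08), but the immediate early genes Egr1 (ratio 3.16), Ier2 (2.21) and Fos (2.01), which also respond to tissue digestion, were higher, and with only the members not set by free RNA the median was 0.64. In the Retnlg cluster the oxidative phosphorylation median was -0.21 (1 of 25 higher), and the stress median was above 0 in 3 clusters (0.20, 0.38 and 0.27). The 8 genes named as lowest included the nuclear receptor Nr4a3 (4.28-fold lower), the transglutaminase Tgm2 (4.06-fold), the elongation factor Ell2 (3.23-fold), the repressor Tgif1 (3.13-fold) and the apoptosis gene Bcl2l11 (3.01-fold). Tnfaip6 (3.08-fold), Vps37b (2.85-fold) and Krt81 (2.80-fold) completed them. All 8 were also lower in B lineage cells, among them Tgif1 (165 and 78.6 CPM), Vps37b (86.9 and 27.6 CPM) and Bcl2l11 (64.2 and 31.5 CPM), and Stfa1, a cystatin of neutrophils, was higher (ratio 2.56).

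Monocytes and macrophages were compared next, since both inflammatory and repair-associated macrophages act in healing bone. The class held fewer macrophages and relatively more monocytes in the CGG-Cit library. A macrophage cluster led by C1qa, C1qb and Trem2 held 1189 CGG and 76 CGG-Cit cells, below the minimum of 100 cells set for gene levels, and a monocyte cluster with Ccr2 and F13a1 among its top genes held 435 and 441. Alternative activation genes had 2 of 15 members higher and a median log2 ratio of -3.40 (-3.82 to -3.10), below all 10000 random lists. At a common mix of the 2 clusters the median was -1.58 (-1.92 to -1.42), with -1.57 in the macrophage cluster and -0.76 in the monocyte cluster, where the summed level was close (1176 and 1188 CPM).

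The lower genes of this class included several of tissue macrophages and osteoclasts. Folr2 (ENSMUSG00000032725; chromosome 7, 101839988 to 101857194), a marker of resident macrophages, had 135 and 3.08 CPM (43.8-fold lower, 26.1 to 80.3), and the growth factors Gas6 and Igf1 were 41.0-fold and 29.1-fold lower. Mmp12, macrophage elastase, was 228-fold lower (140 to 399), Gpnmb 18.2-fold and Pf4 31.5-fold. Atp6v0d2 (59.8-fold lower) and Ctsk (57.8-fold), which take part in bone resorption, and the chemokine Ccl8 (40.7-fold) were also lower. Spp1 (ENSMUSG00000029304; chromosome 5, 104435118 to 104441050) had 2612 and 86.8 CPM, 30.1-fold lower (27.3 to 33.3). The 8 genes named as lowest were also lower in B lineage cells, at far lower levels than in this class. Among them were Mmp12 (18.4 and 0 CPM), Ccl8 (28.0 and 0.0914 CPM) and Spp1 (78.5 and 11.6 CPM). The genes named as highest included Hp (ratio 6.83, 6.44 to 7.24), Nfe2 (5.91), Gpr141 (5.30), Ifitm6 (5.26), Vcan (5.19), Chil3 (5.09) and Plac8 (719 and 3586 CPM, ratio 4.99). With at least 500 detected genes per cell the log2 ratios of these 7, from 2.32 to 2.77 before, were 1.86 for Hp, 1.63 for Nfe2, 1.26 for Gpr141, 1.06 for Ifitm6, 0.99 for Vcan, 1.08 for Chil3 and 1.68 for Plac8. In the same setting Ctsk was -3.37 instead of -5.79, while Mmp12 (-9.36), Ccl8 (-6.90), Folr2 (-6.98), Pf4 (-6.21), Gas6 (-6.40) and Spp1 (-5.88) were further from 0.

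Other gene groups of this class were also lower for the most part. Antigen presentation genes had 2 of 15 members higher (median -0.84, -0.88 to -0.81), with the MHC class II genes H2-Eb1 (3.80-fold lower), H2-Ab1 (3.09-fold) and H2-Aa (3.06-fold). Recruitment ligands had 6 of 16 higher (-0.53, -0.80 to -0.32), with Igf1, Pdgfa (18.4-fold lower) and Tnf (9.14-fold). Neutrophil chemoattraction genes had 5 of 13 higher (-0.74, -0.86 to -0.64), with the neutrophil chemokines Cxcl1 (46.0-fold lower) and Cxcl2 (5.14-fold) and, in the other direction, the leukotriene receptor Ltb4r1 (ratio 4.21). Pro-inflammatory genes had 5 of 16 higher (-0.23, -0.43 to -0.16), with Cxcl9 3.80-fold and Nfkbiz 2.18-fold lower. Dissociation stress genes had 7 of 20 higher (-0.23, -0.26 to -0.20), and the heat shock genes Hspa1a and Hspa1b were 9.64-fold and 9.22-fold lower. Cell cycle genes had 12 of 17 higher (0.71, 0.52 to 0.87), with Hmgb2 (ratio 2.92), Ube2c (2.46) and Cks2 (2.41). These 3 genes stood higher in B lineage cells, at 3326 and 4846, 317 and 596, and 362 and 591 CPM. In the class they stood at 344 and 1005, 21.2 and 52.2, and 61.0 and 147 CPM, so B lineage RNA was not ruled out. At a common mix of clusters the medians were -0.39 for antigen presentation, -0.45 for chemoattraction, -0.45 for the pro-inflammatory list and 0.29 for the cell cycle. With at least 500 detected genes per cell the pro-inflammatory and recruitment ligand medians were -1.17 and -1.29, and with doublets kept the cell cycle median was 1.97. In the macrophage cluster the pro-inflammatory and chemoattraction medians were -0.04 (-0.22 to 0.22) and -0.07 (-0.20 to 0.08), with a higher summed pro-inflammatory level (4476 and 7058 CPM), against -0.73 and -0.76 in the monocyte cluster. By cluster the cell cycle median was 1.55 in the macrophage cluster and -0.26 (-0.44 to -0.04) in the monocyte cluster.

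Interferon response genes had 7 of 23 members higher in the whole class (median -0.28, -0.36 to -0.22), and the median was -1.13 with doublets kept, -0.90 at resolution 0.5 and -1.60 with at least 500 detected genes per cell. This direction turned once the mix of clusters was held level. The median was 1.24 (1.16 to 1.32) at a common mix, with 23 of 23 members higher, 1.48 (1.38 to 1.54) in the macrophage cluster, on 76 CGG-Cit cells, and 0.14 (0.01 to 0.29) in the monocyte cluster. Ifi44 (2.64-fold lower) and Bst2 (2.03-fold) were lower over the whole class, while Isg20 had a ratio of 1.99. Energy metabolism lists differed little over the whole class. Tricarboxylic acid cycle genes had 13 of 23 members higher (0.10, -0.002 to 0.19), with Idh1, the cytosolic isocitrate dehydrogenase, at a ratio of 2.04 (1.87 to 2.22). Oxidative phosphorylation genes had 18 of 25 higher (0.15, 0.12 to 0.20), glycolysis genes 8 of 16 (0.01, -0.08 to 0.08) and citrate and acetyl-CoA genes 5 of 8 (0.05, -0.21 to 0.15). In the monocyte cluster the citrate and acetyl-CoA median was -0.43 (-0.59 to -0.21), and in the macrophage cluster the tricarboxylic acid cycle median was -0.22. With at least 500 detected genes per cell the tricarboxylic acid cycle median was 0.41 and the oxidative phosphorylation median 0.32.

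**Figure D3:**
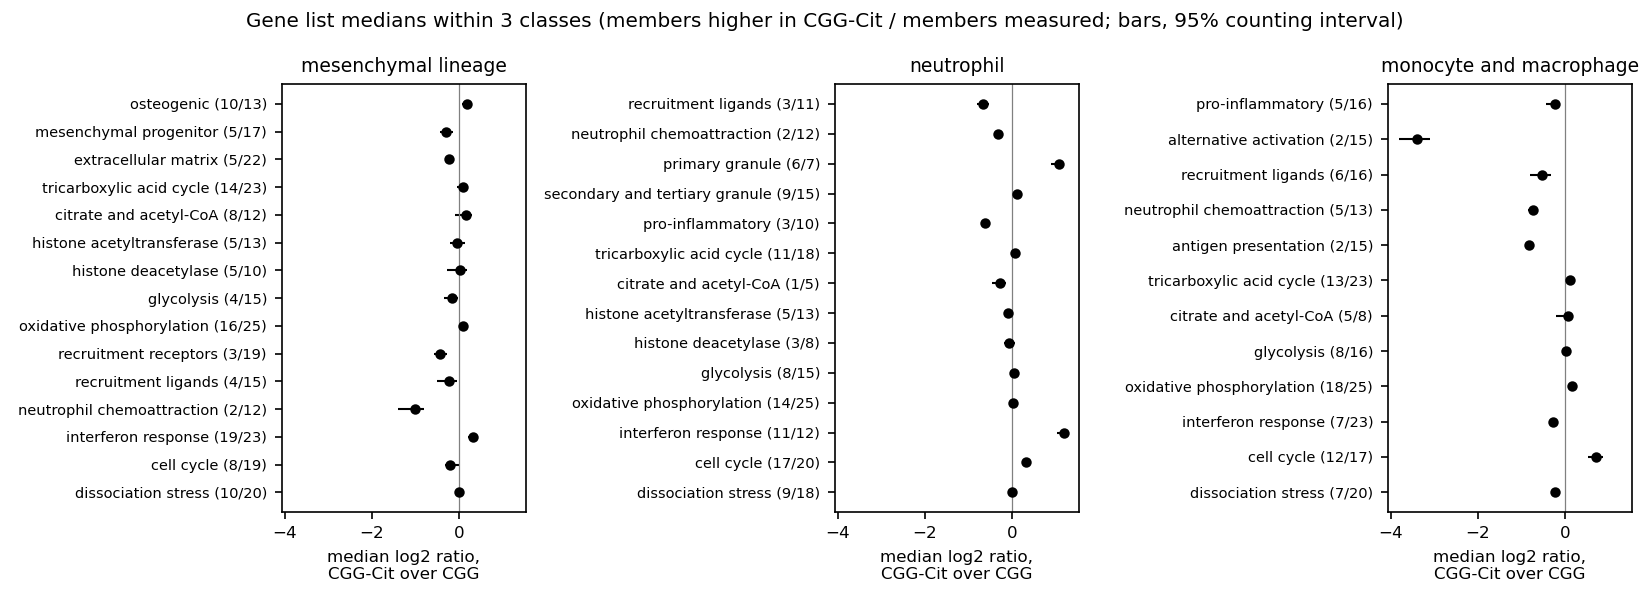
Median log2 ratio (CGG-Cit over CGG) of each gene list in the mesenchymal lineage, neutrophils, and monocytes and macrophages, 1 library per group, with 95% counting intervals as bars and the members higher with CGG-Cit over the members measured in brackets. Alternative activation in monocytes and macrophages (-3.40) and interferon response in neutrophils (1.19) lie at the ends of the scale.

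The mesenchymal lineage was compared to address the osteogenesis and recruitment named in the title. It rests on 62 CGG-Cit cells, below the minimum of 100 cells set for gene levels, with a median of 17970.5 UMIs against 2806 UMIs in the 3780 CGG cells, and 40 of the 62 cells belonged to a cluster led by Ptgds and Mmp13 (537 CGG cells). Over the lineage Ptgds was lower with CGG-Cit (765 and 109 CPM), and the cluster's top genes come mostly from its CGG cells. Its cells in the 2 libraries may therefore differ in kind, which was not tested. Osteogenic genes had 10 of 13 members higher and a median log2 ratio of 0.18 (0.06 to 0.31), above 93.8% of random lists. The lineage leaves out unnamed cluster 6 (992 CGG and 26 CGG-Cit cells), whose best-scoring marker list was osteoblast, with under 3 markers detected. The median therefore does not cover those cells. With each library clustered alone, a CGG cluster led by Mmp13 and Gpha2 was named osteoblast (419 cells, 3.79%), and no CGG-Cit cluster was. In the Ptgds cluster alone 5 of 16 were higher and the median was -0.33 (-0.52 to -0.20). Alpl (ENSMUSG00000028766; chromosome 4, 137741733 to 137796384), the alkaline phosphatase of mineralizing cells, had 48.1 and 121 CPM (ratio 2.51, 2.09 to 2.999). The matrix genes Tnn (ratio 3.49) and Postn (2.12) were higher too, whereas Spp1 was 2.74-fold lower.

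Progenitor, matrix and receptor genes of the mesenchymal cells were mostly lower with CGG-Cit. Mesenchymal progenitor genes had 5 of 17 members higher (median -0.30, -0.43 to -0.14), with the surface markers Cd44 (3.78-fold lower) and Thy1 (3.58-fold). Exceptions were Six2 (ratio 2.88) and Cxcl12 (ENSMUSG00000061353; chromosome 6, 117168535 to 117181367), the chemokine that retains and attracts progenitors, at 172 and 744 CPM (ratio 4.32, 4.01 to 4.65); without the clusters led by Gm26870 its log2 ratio was 1.45 instead of 2.11. Extracellular matrix genes had 5 of 22 higher (-0.24, -0.28 to -0.19), with Timp1 (2.74-fold lower) and Fbn1 (1.91-fold) against Fmod (ratio 1.74). Recruitment receptors had 3 of 19 higher (-0.44, -0.57 to -0.28), with the integrin Itga5 3.28-fold and the Cxcl12 scavenger receptor Ackr3 2.20-fold lower. Recruitment ligands had 4 of 15 higher (-0.23, -0.51 to -0.04), and this direction turned at resolution 0.5 (0.09), without the clusters led by Gm26870 (0.02) and in the Ptgds cluster (0.11), and was -0.02 with only the members not set by free RNA. Neutrophil chemoattraction genes had 2 of 12 higher (-1.02, -1.39 to -0.81), with Cxcl2 6.00-fold, Ccl4 5.34-fold and Cxcl1 2.55-fold lower, but in the Ptgds cluster the median was 0.19 (-0.19 to 0.59). These 3 genes were also lower in B lineage cells (Cxcl2 58.9 and 14.0 CPM, Ccl4 49.6 and 12.6 CPM, Cxcl1 16.5 and 0.183 CPM), and the 3 members not set by free RNA had a median of -1.34. In that cluster the progenitor and matrix medians were -0.62 and -0.55.

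Besides Cxcl12, the genes named as highest in the mesenchymal lineage were Hp (ratio 7.51, 6.65 to 8.47), Cystm1 (4.72), Penk, the precursor of enkephalins (4.72), Crispld1 (4.42), Smoc1 (3.82), Atp1b1 (3.74) and Tspan13 (3.49). Hp was also higher over all kept cells (217 and 599 CPM). Atp1b1 (110 and 412 CPM) and Tspan13 (77.6 and 271 CPM) stood at 626 and 570 CPM and at 353 and 245 CPM in B lineage cells, so B lineage RNA in these cells was not ruled out. The lowest were Retnla (1532 and 0 UMIs, at least 19.1-fold lower against a floor of 3 UMIs in the class; log2 ratio -4.76 without the clusters led by Gm26870 instead of -6.84) and Dmkn (1929 and 2 UMIs, ratio 0.0277, 0.00335 to 0.1003). Ptgds, prostaglandin D synthase, was 7.001-fold lower, the transcription factor Osr2 6.27-fold, Cav1 4.77-fold, Sbsn 4.56-fold, Medag 4.51-fold and Ccl8 4.35-fold. All of these but Dmkn were also lower in B lineage cells, among them Ccl8 (28.0 and 0.0914 CPM), Ptgds (22.5 and 0.0457 CPM) and Retnla (13.9 and 0.0914 CPM). The macrophage gene C1qa stood at 195 and 0.888 CPM in these cells, and in B lineage cells at 80.2 and 0.549 CPM. S100a8, a neutrophil gene, stood at 3068 and 5458 CPM.

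**Figure D4:**
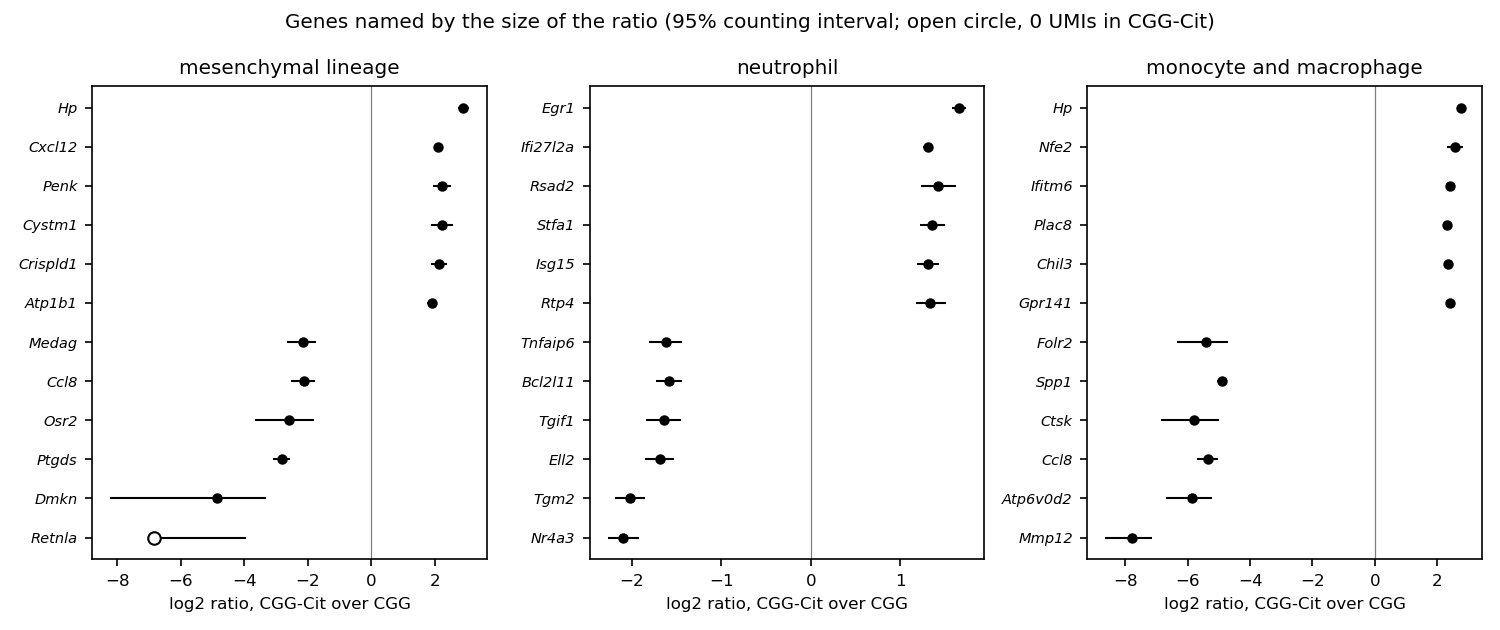
Log2 ratio (CGG-Cit over CGG) of the 6 highest and 6 lowest genes chosen by the size of the ratio in each of 3 classes, 1 library per group, with exact 95% counting intervals as bars; the open circle is a gene with 0 UMIs with CGG-Cit, drawn with 0.5 UMI added. Mmp12 in monocytes and macrophages is the lowest point, 228-fold lower with CGG-Cit.

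The title also points to tricarboxylic acid cycle metabolites and histone acetylation, and the lists for these showed small or undetectable differences in the mesenchymal lineage. Histone acetyltransferase genes had 5 of 13 members higher (median -0.06, -0.20 to 0.13), and Ep300 (ENSMUSG00000055024; chromosome 15, 81585351 to 81652077), a histone acetyltransferase, had 63.6 and 59.5 CPM (ratio 0.935, 0.722 to 1.19). Brd2 and Brd3, readers of acetylated histones, had ratios of 1.35 and 0.759, and the acetyltransferase Kat2a had 0.503 (0.201 to 1.05). Histone deacetylase genes had 5 of 10 higher (0.02, -0.28 to 0.19), with Hdac7 at 0.520 and Hdac1 at 1.26 (0.990 to 1.59). Citrate and acetyl-CoA genes had 8 of 12 higher (0.16, -0.09 to 0.29). Acly (ENSMUSG00000020917; chromosome 11, 100476353 to 100528000), which makes acetyl-CoA from citrate, was lower at 48.9 and 24.0 CPM (ratio 0.491, 0.322 to 0.717). The mitochondrial citrate carrier Slc25a1 had a ratio of 1.22 (0.862 to 1.68), and the plasma membrane citrate transporter Slc13a5 had 26 and 2 UMIs (ratio 2.06, 0.237 to 8.21).

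Tricarboxylic acid cycle genes had 14 of 23 members higher (median 0.08, -0.05 to 0.19), with Suclg1 at a ratio of 1.30. Oxidative phosphorylation genes had 16 of 25 higher (0.09, 0.01 to 0.13), with Ndufa4 at 1.41, and glycolysis genes 4 of 15 (-0.17, -0.35 to -0.04), with Hk2 at 0.578. Interferon response genes had 19 of 23 higher (0.31, 0.21 to 0.38), with Rsad2 at 2.22 and Ifit3b at 1.93, and in the Ptgds cluster the median was 0.01. Cell cycle genes had 8 of 19 higher (-0.21, -0.32 to 0.02), but 16 of 17 in the Ptgds cluster, where the median was 1.78 (1.36 to 2.03). The cell cycle median was also above 0 at resolution 0.5 (0.67), without the clusters led by Gm26870 (0.52), with at least 500 detected genes per cell (0.14) and with doublets kept (0.12). In B lineage cells 20 of 20 members were higher. Hmgb2 stood at 3326 and 4846 CPM there, against 328 and 469 CPM in the mesenchymal lineage, and Stmn1 at 1072 and 1834 against 84.8 and 141 CPM. Mki67, higher in B lineage cells (534 and 817 CPM), was lower in the lineage (62.5 and 47.1 CPM). B lineage RNA in these cells was not ruled out. Dissociation stress genes had 10 of 20 higher (-0.01, -0.06 to 0.08), with Klf2 at 1.91 and Hspa1b at 0.612.

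Endothelial cells showed the interferon difference as well, on only 46 CGG-Cit cells, again fewer than the set minimum. Interferon response genes had 22 of 23 members higher (median 1.06, 0.99 to 1.25), with Ifit3b at a ratio of 3.51 (2.69 to 4.56), Ifi44 at 3.18 and Usp18 at 2.92. Angiogenesis genes had 14 of 19 higher (0.32, 0.14 to 0.42), with the junction protein Pecam1 at 714 and 1228 CPM and the apelin gene Apln at a ratio of 1.63, while Vegfa was 4.61-fold lower and the tip cell gene Esm1 3.70-fold; with doublets kept the median was 0.15. Dissociation stress genes had 1 of 20 higher (-0.78, -0.87 to -0.66), and Hspa1b was 9.69-fold lower. Antigen presentation genes had 6 of 14 higher (-1.06, -1.78 to -0.53), with Cd74 at 723 and 14.9 CPM, but with only the members not set by free RNA the median was 0.50. Of the 690 CGG cells, 489 were in a cluster that held 1 CGG-Cit cell, and C1qa stood at 410 CPM in CGG endothelial cells and was not detected in the CGG-Cit ones.

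Cxcl12 and its receptor Cxcr4 were followed across classes because they link stromal cells to recruited leukocytes and progenitors. Cxcl12 was highest in endothelial cells, at 772 CPM with CGG and 786 CPM with CGG-Cit (ratio 1.02, 0.917 to 1.13), and was higher in the mesenchymal lineage as given above. In the haematopoietic classes it stayed at 9.82 CPM or less. Over all kept cells, Cxcl12 had 101 and 14.8 CPM. Cxcr4 (ENSMUSG00000045382; chromosome 1, 128588199 to 128592293) was lower with CGG-Cit in neutrophils (166 and 123 CPM, ratio 0.742, 0.695 to 0.791), in monocytes and macrophages (ratio 0.597, 0.550 to 0.646), in T and NK cells (0.677, 0.620 to 0.738), in B lineage cells (0.738, 0.705 to 0.774) and in dendritic cells (0.771, 0.612 to 0.973). In erythroid cells, myeloid progenitors, and mast cells and basophils the intervals included 1. Cxcr4 was also lower in endothelial cells (0.302, 0.199 to 0.441) and in the mesenchymal lineage (0.561, 0.374 to 0.809), where its CGG level of 46.0 CPM lay below that in the leukocyte classes.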

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

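The settings without the clusters led by Gm26870, with haematopoietic classes only, with the same share of doublets removed, at a common mix of clusters and with the Ptgds cluster (cluster 14) alone were chosen only after the results were seen; all others were planned. No paired analysis was possible because each group has 1 library, so the groups share fewer than 2 replicate numbers and no result comes from a test. Of 83 class differences under planned settings 78 kept their direction and 1 reversed, and of 281 list medians 259 kept it and 2 reversed. For genes named by the size of their ratio and the title's targets, all 159 planned values kept it. Under the added settings these were 27 of 32 differences (2 reversed), 62 of 73 medians (5 reversed) and 52 of 53 gene values (0 reversed). Genes named only from the lists, and Cxcr4, were not tried under other settings. Median-of-ratios scaling moves all genes of a class by the same small amount, so it was a weak check of genes with large ratios. Mesenchymal clusters alone gave the same gene list medians as the lineage, since the main clustering named no cluster osteoblast or chondrocyte. For some lists, among them interferon response and primary granule genes in neutrophils, under 3 members remained once those set by free RNA were left out, so no value was given.

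Differences in percentage points (CGG-Cit minus CGG) moved beyond the counting interval in 43 planned and 19 added cases; those of 4 classes and the largest of others follow, and the cause was not tested. The mesenchymal lineage difference (-33.6) was -11.5 at resolution 0.5, -25.8 at resolution 2.0, -23.2 with doublets kept, -23.4 with at least 500 detected genes, -28.7 with at most 10% mitochondrial UMIs, -38.8 after thinning, -20.6 with separate clustering, -28.5 with the same share of doublets removed and -20.8 without the clusters led by Gm26870. The monocyte and macrophage difference (-9.51) was, for these settings other than thinning, -8.15, -13.1, -6.93, -6.58, -6.82, -1.48, -8.60 and -15.1, and -25.9 with haematopoietic classes only. The neutrophil difference (16.7) was 18.0 with doublets kept, 12.9 without the clusters led by Gm26870 and 7.82 with haematopoietic classes only. The B lineage difference (30.6) was 29.3 with doublets kept, 32.1 with at least 500 detected genes, 27.6 without the clusters led by Gm26870 and 25.0 with haematopoietic classes only. The unnamed difference (-3.17) was -27.3 at resolution 0.5, the T and NK difference (-0.775) -7.63 with haematopoietic classes only, the myeloid progenitor difference (2.06) 5.44 after thinning, the endothelial difference (-5.78) -8.18 without the clusters led by Gm26870, and the dendritic difference (0.0797) -2.99 with separate clustering, -1.85 at resolution 2.0 and -1.70 with doublets kept. Reversed were erythroid cells with haematopoietic classes only (-0.634), myeloid progenitors with separate clustering (-0.837) and unnamed clusters without those led by Gm26870 (4.79). A reversal was counted only where the main difference lay beyond counting error. The dendritic difference, which changed sign, was therefore not counted as reversed.

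Median log2 ratios moved as follows. In neutrophils, recruitment ligands (-0.68) were -1.0 with no minimum level, -0.34 with members not set by free RNA and -0.43 with doublets kept, and interferon response genes (1.19) were 1.29 with size factors, 0.70 with no minimum level and 1.38 at a common mix of clusters. In monocytes and macrophages, alternative activation (-3.40) was -4.20 with doublets kept, -4.08 at resolution 0.5, -4.89 with at least 500 detected genes and -1.58 at a common mix, and interferon response (-0.28) was -1.13, -0.90 and -1.60 for the first 3 of these and reversed to 1.24 at a common mix. In the mesenchymal lineage, the Ptgds cluster alone reversed the osteogenic (-0.33), recruitment ligand (0.11) and chemoattraction (0.19) medians, and recruitment ligands also reversed at resolution 0.5 (0.09) and without the clusters led by Gm26870 (0.02). Endothelial antigen presentation reversed to 0.50 with members not set by free RNA. The common mix gives both libraries the same shares of clusters, but it also weights clusters by cells instead of UMIs. A move in that setting therefore cannot be put down to the mix alone. For the other settings the cause was not tested. The mesenchymal lineage and endothelial results rest on 62 and 46 CGG-Cit cells.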

Other observations

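Osteocalcin RNA was concentrated in very few cells. Bglap, the osteocalcin gene and a marker of mature osteoblasts, had 18045 UMIs in all kept CGG cells and 20 in CGG-Cit cells. In the CGG library 9 of 11048 cells (0.0815%, exact 95% interval 0.0373 to 0.155%) held at least 10 Bglap UMIs each, and together 92.6% of all Bglap UMIs. Of these 9 cells 6 lay in unnamed cluster 6 and 3 in the Ptgds cluster 14. In the CGG-Cit library 0 of 9971 cells did, with an exact upper limit of 0.0370%, just below the CGG interval, so the comparison rests on 9 cells. Clusters 6 and 14 held only 26 and 40 CGG-Cit cells, against 992 and 537 CGG cells. These are too few to show whether cells rich in Bglap were lacking beyond the lower number of stromal cells.

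An Il17a cluster with Cd163l1, Cxcr6 and Icos, genes typical of gamma delta T cells that make interleukin 17, held 181 CGG cells (1.64%) and 66 CGG-Cit cells (0.662%). Il17a, the interleukin that drives neutrophil mobilisation, had 195 CPM in CGG and 109 CPM in CGG-Cit T and NK cells (664 and 333 UMIs). NK cells marked by Gzma and Ncr1 went the other way, with 95 and 168 cells (0.860% and 1.68% of kept cells). Plasmacytoid dendritic cells marked by Siglech and Ccr9 numbered 51 and 85, and migratory dendritic cells marked by Ccr7 and Ccl22 numbered 51 and 15. A lower stromal share alone would raise the shares of leukocytes, so the NK and plasmacytoid numbers do not show a rise among haematopoietic cells. The gene model Gm26870 had 194 CPM over all CGG cells and 3.09 CPM over all CGG-Cit cells, and it stood at 193 and 8.05 CPM in neutrophils, 198 and 1.05 CPM in B lineage cells and 182 and 6.22 CPM in the mesenchymal lineage.

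The marrow lineages were higher and the stromal classes lower in the CGG-Cit library; all tests of explanations in this part were chosen only after the results were seen. Shallow CGG barcodes were not the whole cause, since without the clusters led by Gm26870 the mesenchymal difference was still -20.8 percentage points (-21.7 to -19.9). Fewer stromal cells over an unchanged haematopoietic mix were not the whole cause either, since among haematopoietic classes the B lineage difference was 25.0 percentage points (23.5 to 26.4). More bone marrow in the trimmed tissue may account for it, but shares of all kept cells cannot decide this. B lineage, neutrophil, erythroid and myeloid progenitor shares of all kept cells were each higher, by ratios of at least 1.85. A lower stromal share alone would also raise the shares of haematopoietic classes, so these ratios are no support for more marrow. Among haematopoietic classes only, the erythroid share was not higher (-0.634 percentage points, -1.75 to 0.455), unlike the B lineage share. Shares within these classes depend on one another, so this does not decide the explanation. With separate clustering the myeloid progenitor difference was -0.837 (-1.29 to -0.384). Clusters were named in each library alone there, so the name may cover different cells. The hydrogel and the dissection differ between the same 2 libraries, so more marrow and an effect of the hydrogel cannot be told apart.

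Interferon response genes were higher in CGG-Cit neutrophils. A different mix of neutrophil clusters was excluded as the cause, since the median log2 ratio at a common mix was 1.38 (1.17 to 1.47). Free RNA reaching all classes alike was excluded as the whole cause, since the summed level differed by -126 CPM in B lineage cells (-148 to -105) and by 365 CPM in neutrophils (347 to 383), but erythroid cells differed as much (358 CPM, 324 to 391) and under 3 neutrophil members remained once those set by free RNA were left out, so a part played by free RNA stays open. A shift of like size in every class was excluded, since the median at a common mix was -0.18 (-0.33 to 0.06) in B lineage cells and -0.56 (-0.87 to -0.34) in dendritic cells, the latter with only 15 CGG-Cit cells in 1 of its 2 clusters; of 6 classes 4 lay above 0, 1 below and 1 reached 0. A stronger interferon response of neutrophils in the CGG-Cit defects may be a candidate explanation and was not tested. It would not be particular to neutrophils. The list was also higher in the macrophage cluster (1.48), though not over its whole class (-0.28), and in endothelial cells (1.06, 46 CGG-Cit cells). Whether it comes from the hydrogel or from a difference between mice, days or library preparation was not tested, with 1 library per group and the kit version of each unknown.

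Alternative activation genes were lower in CGG-Cit monocytes and macrophages. Fewer cells of the macrophage cluster 2 account for part of this and not for all. The median log2 ratio was -3.40 over the class and -1.58 (-1.92 to -1.42) at a common mix. Within clusters it was -1.57 in cluster 2 and -0.76 in the monocyte cluster. Macrophage RNA free in the CGG library was excluded as the whole cause, since the summed level differed by -161 CPM in B lineage cells (-183 to -140) and by -2950 CPM in the class. A less advanced conversion of monocytes to repair macrophages with CGG-Cit may be a candidate explanation, and a different region of tissue trimmed stays open beside it, since neither was tested.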
